A study of Mus musculus with 16 samples.

How the data were processed

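Single-cell RNA was measured in CD45-enriched cells of subcutaneous B16-OVA melanomas of C57BL/6 mice. Per the labels' protocols, 4 treatment groups of 10 mice each received an isotype antibody or anti-PD-1 (10 mg/kg) together with vehicle or an oral TBK1 inhibitor (40 mg/kg daily). The protocols give day 14 for the harvest, although the dosing days they list run to day 18. Tumours were dissociated and passed over a density gradient, and CD45-positive cells were enriched on magnetic beads. Tumours of 4 mice per group went into droplet 3′ libraries, 1 library per tumour, which gave 16 samples. The inhibitor is known here only by a code name, so nothing is said of its structure.

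The deposited values are UMI counts per gene and cell barcode in cell-associated matrices, made with Cell Ranger 3.0.1 against mm10 per the submitters' processing notes. The matrices were whole numbers with 31053 features in each of the 16 libraries and 106949 barcodes together. A second deposited matrix of each library held the same values in all 16 libraries. Features that share a symbol (71) were told apart by their Ensembl identifier. Coordinates are those of GENCODE release M21 on mm10 (GRCm38), counted from 1. Replicate numbers follow the labels' titles, since 3 file names of the anti-PD-1 group carried other numbers. The labels name version 2 of the library chemistry, while the barcodes are of the kind used by a later version. Whether this bears on the 5 libraries set apart in the results was not tested.

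Barcodes with at least 200 genes and at most 20% mitochondrial UMIs (95999) were clustered. Doublets were scored per library as the share of simulated doublets among the nearest neighbours, and the highest-scoring barcodes were removed at a rate of 0.8% per 1000 barcodes. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 nearest neighbours fed Leiden clustering at resolution 1.0. T and NK clusters were clustered again. Clusters were called by the markers of the class they resembled, as "-like" cells. The markers, the 19 gene lists, the tests, the rule for named genes and the alternative settings were fixed before the data were examined. The thresholds of the naming score were set after seeing the data, at a marker score of 0.28, at most 25% predicted doublets, a leading gene seen in 10% of cells, a gap of 0.05 between CD8 and CD4 scores, and at most 60% of cells with Lyz2 in a T or NK cluster. Those thresholds kept 3 kinds of clusters out of the classes. Clusters with a low marker score held 8.50% of the retained cells in control, 5.46% under anti-PD-1, 1.12% under TBK1i and 0.980% under the combination. Clusters of mixed cells held 1.97%, 3.59%, 6.40% and 5.18% in the same order, and T cells resolved as neither CD8 nor CD4 held 2.19%, 1.75%, 2.16% and 7.64%. A small cluster with few UMIs, named for none, held 0.0751%, 0.0133%, 0.894% and 0%.

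Tests used cells with at least 250 genes and at most 10% mitochondrial UMIs. Counts were summed per library and class over monocyte/macrophage-like, conventional dendritic (cDC-like), CD8 T-like and NK-like cells. A library with fewer than 20 cells of a class was left out of that class, and a contrast needed at least 3 libraries per group. Values are given as counts per 1000000 (CPM) after TMM scaling, as mean ± SD over libraries. Changed genes were called with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the robust quasi-likelihood test on genes passing filterByExpr, with all libraries in 1 fit, Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera on log2 CPM (prior count 2) at the preset correlation of 0.01, adjusted over all lists and classes of a contrast, and again with an estimated correlation. Unless another tool is named, an adjusted p of a gene is edgeR's and one of a list is camera's. Shares of the named immune classes were compared with two-sided exact permutation tests over the 70 relabellings of 4 libraries against 4, whose smallest p is 0.029. Effects averaged over the other treatment were permuted within its levels, over 4900 relabellings. Share p-values were adjusted by Benjamini-Hochberg over classes and comparisons. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

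The genes named were chosen by a rule. For each of 4 pairwise contrasts and each class it took up to 4 genes higher and 4 lower with the largest fold change among those past the threshold, with a mean of at least 20 CPM and no overlap between the libraries of the groups. Predicted genes, mitochondrial, ribosomal, variable receptor, haemoglobin and sex-linked genes were left out. To these came 2 to 4 members with the smallest p of each list described, and genes of prior interest with at least 5 CPM. Not every gene the rule took is named in the text. Ltb and Ifnb1 fall outside the rule and were chosen after their values were seen. Counts of genes with near-identical copies, among them H2-Q6 and H2-Q7, Hspa1a and Hspa1b, Amd1 and Amd2, Ifit1 and Ifit1bl1, and the linker histones, are uncertain because reads could fall to either copy.

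The edgeR, DESeq2 and camera steps were tested on simulated counts. These took the means pooled over all libraries of a class, with the real dispersions and library sizes. In them 200 genes were changed between TBK1i and control, and no library set apart was simulated. The permutation test was tested on values drawn from a normal distribution. Of 100 genes changed 4-fold, edgeR recovered 92 in monocyte/macrophage-like cells (11157 genes fitted), 93 in cDC-like (6178), 73 in CD8 T-like (8125) and 82 in NK-like cells (2860), with 10, 8, 4 and 6 false calls. Of 100 changed 2-fold it recovered 70, 52, 37 and 27. DESeq2 recovered 93, 92, 67 and 73 of those changed 4-fold and 76, 46, 36 and 18 of those changed 2-fold, with 31, 8, 5 and 4 false calls. Camera found the planted list in each class and gave an unplanted list p of 0.85, 0.861, 0.214 and 0.534. Genes were drawn independently of each other, so this does not test camera where the genes of a list are correlated. The exact test called 3.25% of 400 draws without a difference and 99.5% of draws with a difference of 5 SD.

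The alternative settings fixed at the start were RLE size factors, the Wald test of DESeq2 1.42.0, no filter on low counts, the replicate number as a block, only the groups of the contrast in the fit, looser and stricter cell filters (at most 20% mitochondrial UMIs with at least 200 genes, or at least 500 genes), doublets kept, resolution 2.0, each library left out, all retained cells as the denominator, an edgeR test of cell numbers, and the estimated correlation. Those chosen after seeing the data were a term for the library set described in the results, TBK1i replicate 4 and control replicate 4 left out together, unresolved T cells counted as CD8 T, and the shared direction of genes without TBK1i replicate 4. RLE scaling moved the median fold change over all genes by at most 0.04 on the log2 scale, and turned the median of no list past its threshold. Contrasts of CD8 T-like cells with the combination were not tested because 3 of its 4 libraries held fewer than 20 such cells. Cell types other than the 4 tested classes were compared as shares alone, and receptor sequences, splicing and cell-cycle phase were not analysed here.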

Results

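Droplet 3′ RNA sequencing of CD45-enriched cells from B16-OVA tumours, a mouse melanoma line that carries ovalbumin, gave 16 libraries of UMI counts. They fall into 4 groups of 4. Control mice had isotype antibody and vehicle, anti-PD-1 mice the antibody and vehicle, TBK1i mice isotype antibody and a TBK1 inhibitor, and combination mice both treatments. Anti-PD-1 blocks an inhibitory receptor of T cells, and TBK1 is a kinase that acts in interferon induction and in signalling from TNF receptors. The design asks what each treatment did alone and what both did. Total counts in replicates 1 to 4 were 30351071, 35709463, 19360627 and 37077650 in control and 41165985, 36318377, 37762175 and 29669365 under anti-PD-1. They were 25309321, 58427425, 49551341 and 29035716 under TBK1i and 5180135, 8034704, 12801645 and 37200276 under the combination. After filtering, 1465 to 10836 cells per library were kept. The means were 3948 in control, 4781 under anti-PD-1, 4618 under TBK1i and 5266 under the combination. The median UMI count of a kept cell averaged 3138 ± 1639 in control, 3091 ± 1021 under anti-PD-1, 4794 ± 1906 under TBK1i and 1951 ± 582 under the combination (SD, n = 4 each).

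In 5 libraries, TBK1i replicate 4 and all 4 combination libraries, transcripts of ribosomal proteins stood apart from the other 11 in monocyte/macrophage-like, cDC-like and NK-like cells. The SD of the log2 deviations over ribosomal protein genes was 0.665 to 0.859 in these 5 libraries and 0.111 to 0.402 in the others. In monocyte/macrophage-like cells Rpl12 differed from the other libraries by -2.55 on the log2 scale, while Rpl38 lay higher by 1.29 and Rps28 by 1.14. Because all 4 combination libraries belong to this set, the set and the combination cannot be told apart. A fit with the set as a term rests on TBK1i replicate 4 alone. Anti-PD-1 against control lies within the other 11 libraries, and TBK1i against control does so without TBK1i replicate 4. RNA of other cells also differed between groups. Melanoma transcripts made up 5656 ± 2498 CPM of the libraries in control, 7619 ± 2670 under anti-PD-1, 4637 ± 3217 under TBK1i and 181 ± 133 under the combination (SD, n = 4 each). The exact two-sided permutation p was 0.029 for the combination against control. Melanoma-like cells were 24.1% ± 13.9, 23% ± 13, 7.57% ± 6.10 and 0.055% ± 0.085 of the retained cells in the same order (SD, n = 4). They were 0.31% in TBK1i replicate 4.

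**Figure D1:**
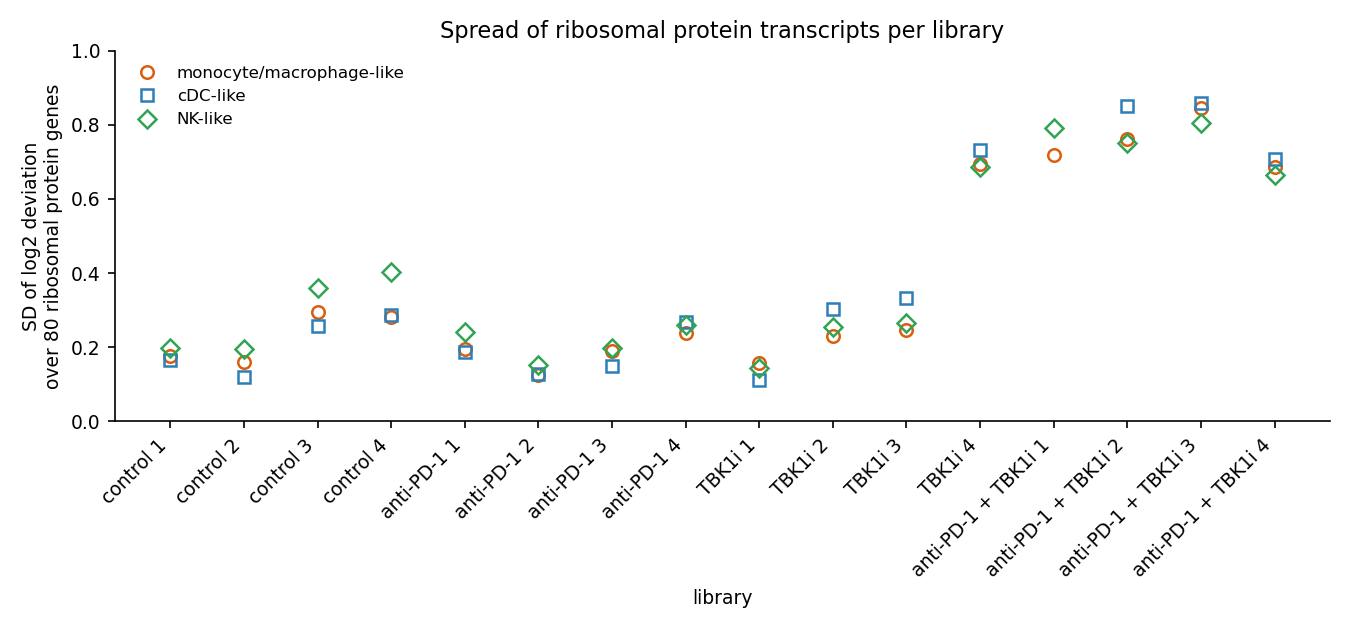
Spread of ribosomal protein transcripts per library: the vertical axis is the SD of log2 deviations over ribosomal protein genes, the horizontal axis the libraries by group, and each marker is a cell class of 1 library. The 5 libraries of the set (TBK1i replicate 4 and the combination) lie between 0.665 and 0.859 and the other 11 between 0.111 and 0.402.

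The share of each class among named immune cells shows how the infiltrate differed, under CD45 bead enrichment, a density gradient that removes part of the granulocytes, and unequal depth. CD8 T-like cells were 10.4% ± 2.03 of immune cells in control, 25.5% ± 3.00 under anti-PD-1, 2.71% ± 1.29 under TBK1i and 0.286% ± 0.248 under the combination (SD, n = 4 each). All 4 anti-PD-1 libraries lay above all 4 control libraries, and all TBK1i and combination libraries below them. Each of these 3 differences from control had an exact permutation p of 0.029 and an adjusted p of 0.060, which misses 0.05. Under anti-PD-1 neutrophil-like cells were 1.18% ± 0.683 against 4.28% ± 1.88 in control (SD, n = 4, exact permutation p = 0.029, adjusted p = 0.060). The log2 ratio of CD8 T to regulatory T-like cells was 4.02 ± 0.20 against 2.25 ± 0.72 (SD, n = 4), with the same exact permutation p and adjusted p. Under TBK1i that ratio was -0.35 ± 0.69 (SD, n = 4). The log2 ratio of lymphoid to myeloid cells was -2.66 ± 0.30 against -1.45 ± 0.55 in control (SD, n = 4). Both had an exact permutation p of 0.029 and an adjusted p of 0.060. Regulatory T-like cells were 2.26% ± 0.81 of immune cells in control and 3.28% ± 1.73 under TBK1i (SD, n = 4, exact permutation p = 0.31). Within the 11 libraries, without TBK1i replicate 4, CD8 T-like cells were 3.34% ± 0.243 under TBK1i (SD, n = 3). That is a difference of -7.01 percentage points (exact permutation p = 0.029).

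T cells resolved as neither CD8 nor CD4 were 4.55% of immune cells in control and 8.23% under the combination, and the median UMI count of T-like cells was 1005 ± 266 there against 3605 ± 1213 (SD, n = 4). Counted together with CD8 T-like cells they made 14.9% ± 1.18 in control, 28.1% ± 3.31 under anti-PD-1, 5.22% ± 0.705 under TBK1i and 8.52% ± 2.48 under the combination (SD, n = 4). The combined share thus differed from control by 13.2, -9.68 and -6.39 percentage points, each with an exact permutation p of 0.029. This combined share overlapped between the combination (4.85% to 10.2%) and TBK1i alone (4.47% to 6.13%), and that difference was not tested. Averaged over the antibody, CD8 T-like cells were fewer in the inhibitor groups (difference -16.5 percentage points, adjusted p = 0.0030 in the exact permutation test). The CD8 to regulatory T ratio was lower too (-4.75 on the log2 scale, adjusted p = 0.0030). Both differences leave out the unresolved T cells. Combination replicates 1 to 4 held 9, 6, 4 and 22 CD8 T-like cells beside 128, 311, 234 and 882 unresolved T cells. The lymphoid to myeloid ratio fell by 1.55 on the log2 scale (adjusted p = 0.0030). Monocyte/macrophage-like cells rose by 13.0 and neutrophil-like cells by 7.22 percentage points (adjusted p = 0.0054 each, exact permutation). For TBK1i replicates 1 to 3 against control their exact permutation p was 0.11 and 0.14, and that of the ratio 0.029. Averaged over the inhibitor, the antibody groups had fewer cDC-like (-3.71 percentage points, adjusted p = 0.010) and plasmacytoid dendritic-like cells (-0.63 percentage points, adjusted p = 0.014, exact permutation). Of the 8 inhibitor libraries in these averages 5 belong to the set apart. Of 11 shares and ratios, 3 had an exact p under 0.05 for anti-PD-1 against control. There was 1 without any one anti-PD-1 library, and 5 without control replicate 1. Averaged over the inhibitor, the antibody had 2 at an adjusted p under 0.05, and 4 without control replicate 3 or TBK1i replicate 4.

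**Figure D2:**
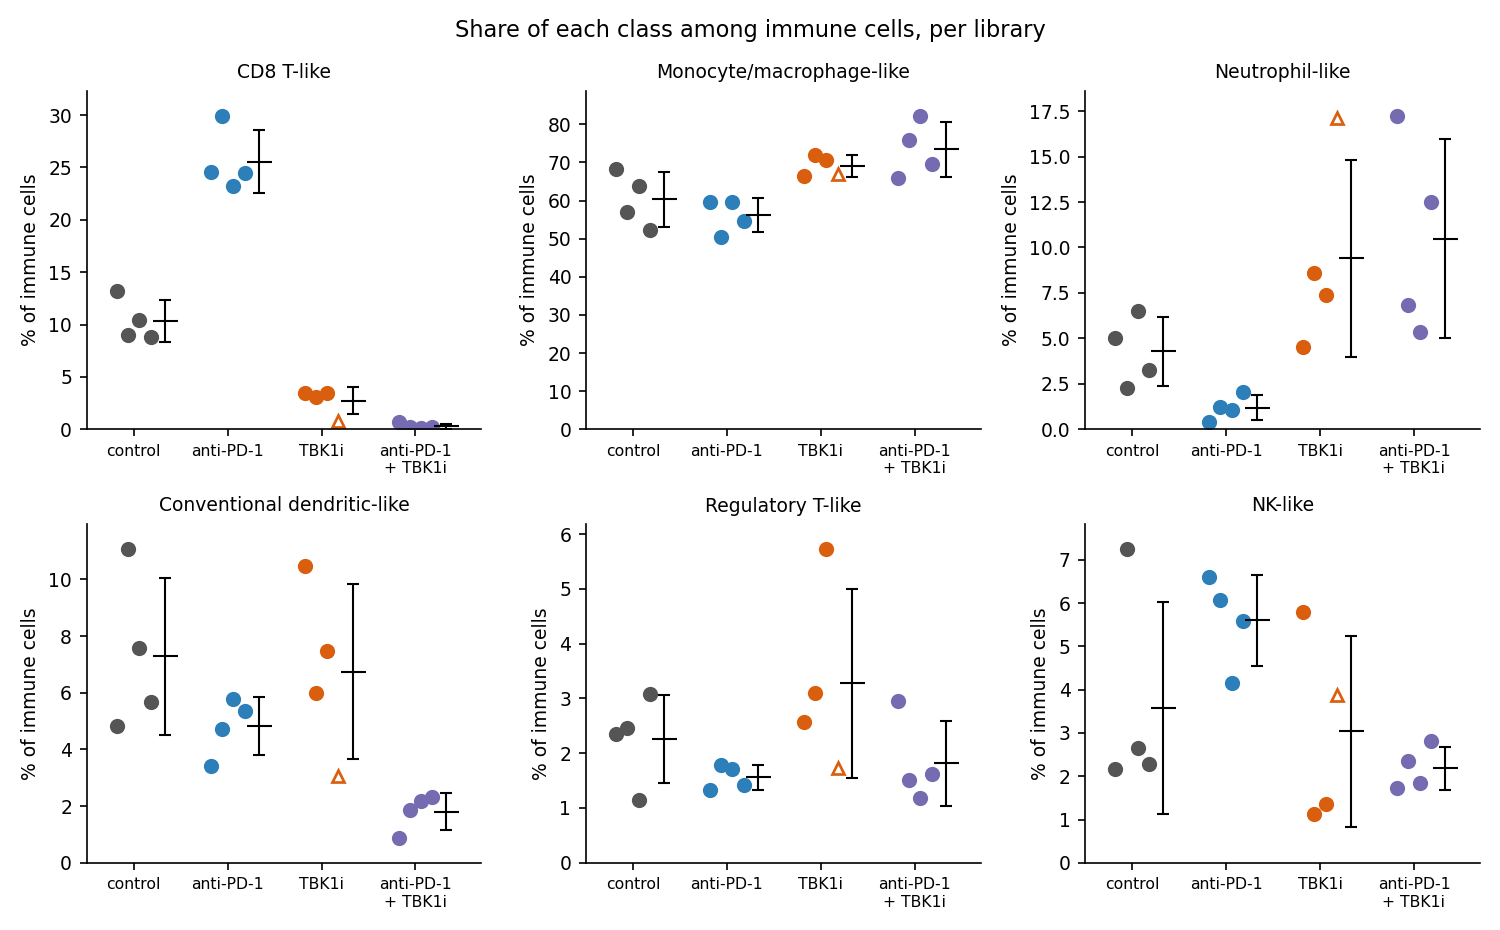
Shares of 6 immune classes: the vertical axis of each panel is the percent of named immune cells and the horizontal axis the 4 groups, each point is a library, and bars give mean and SD (n = 4). CD8 T-like cells averaged 25.5% under anti-PD-1, 10.4% in control, 2.71% under TBK1i and 0.286% under the combination, and the open triangle is TBK1i replicate 4.

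Anti-PD-1 against control asks what PD-1 blockade alone did within each cell class. Gbp2b and Il18bp were higher and Bhlhe41 lower in monocyte/macrophage-like cells. Gbp2b, an interferon-induced GTPase (ENSMUSG00000040264, mm10 chromosome 3, 142594847 to 142619179), stood at 154 ± 23.2 CPM against 18.1 ± 9.36 (SD, n = 4). It rose by 3.08 on the log2 scale (SE 0.45, adjusted p = 0.010). Il18bp, a decoy that binds interleukin 18 (ENSMUSG00000070427, chromosome 7, 102014885 to 102018690), stood at 192 ± 34.2 CPM against 47.1 ± 14.2 (SD, n = 4). It rose by 2.03 (SE 0.29, adjusted p = 0.010). The ganglioside synthase gene St3gal5 rose by 1.14, the kinase gene Nuak2 by 1.36 and Irf8, a transcription factor of myeloid cells, by 1.00 on the log2 scale (adjusted p = 0.023, 0.048 and 0.021). Lower were Bhlhe41, a transcriptional repressor (ENSMUSG00000030256, chromosome 6, 145858243 to 145865558), at 15.4 ± 3.41 CPM against 52.9 ± 19.2 (SD, n = 4, log2 fold change -1.78, SE 0.34, adjusted p = 0.040). Also lower were the hypoxia-induced Ankrd37 (log2 fold change -1.62, adjusted p = 0.040), the collagenase gene Mmp8 (-1.28, adjusted p = 0.048) and Smad7, an inhibitor of TGF-beta signalling (-1.23, adjusted p = 0.048). For these 9 genes the 4 libraries of each group did not overlap. Cxcl9 stood at 799 ± 106 CPM against 471 ± 90.0, Cxcl10 at 539 ± 115 against 248 ± 118, Cd274 at 280 ± 64.4 against 148 ± 40.7 and Nos2 at 211 ± 88.1 against 63.4 ± 30.9 (SD, n = 4). None of these passed the test, whose spread is that of all libraries (adjusted p = 0.57, 0.28, 0.18 and 0.16). A fit of only these groups called more genes. Tbk1 itself stood at 45 ± 5.6 and 37.6 ± 0.917 CPM (SD, n = 4, adjusted p = 0.34).

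The interferon gamma response list rose in these cells (median log2 fold change 1.67). Of its 25 measured genes 2 rose over all genes tested and 24 adjusted over the list alone (adjusted p = 3.2e-18, and adjusted p = 0.29 with an estimated correlation). MHC class I presentation rose by a median of 0.89 (14 of 18 genes adjusted over the list alone, 0 over all genes in edgeR, adjusted p = 6.9e-11, and adjusted p = 0.31 with an estimated correlation). MHC class II presentation rose by 1.19 (8 of 11 adjusted over the list alone, 0 over all genes, adjusted p = 5.1e-08, and adjusted p = 0.26 with an estimated correlation). Type I interferon response genes had a median of 0.71, with 0 of 29 past the test in either way of adjusting (list adjusted p = 3.3e-08, and adjusted p = 0.39 with an estimated correlation). The lists of inflammatory macrophage genes (median 0.68), TNF and NF-kB response (0.40) and RIPK1 and TNF-induced cell death (0.34) also rose. In them 4 of 14, 7 of 24 and 4 of 16 genes were higher adjusted over the list alone, 2 of the 24 lower, and 0 over all genes. Their adjusted p was 4.4e-05, 0.0012 and 5.5e-04, and the adjusted p = 0.34, 0.47 and 0.33 with an estimated correlation. Hypoxia and glycolysis genes fell with a median of -0.50, with 2 of 21 lower over all genes and 11 adjusted over the list alone (adjusted p = 1.0e-07, and adjusted p = 0.31 with an estimated correlation). Proliferation genes had a median of -0.54 with 0 of 23 past the test either way (list adjusted p = 8.8e-05, and adjusted p = 0.48 with an estimated correlation). Alternatively activated macrophage genes did not change as a list (adjusted p = 0.87), and their median of -0.12 and mean of 0.17 differ in sign. T cell RNA in these myeloid cells had a median log2 fold change of 1.06 (adjusted p = 1.2e-05, and adjusted p = 0.34 with an estimated correlation). Stromal RNA had one of 1.53 over 4 genes (adjusted p = 0.016, and adjusted p = 0.34 with an estimated correlation). Cluster 5, led by Gbp2b, Rsad2 and Ifit2, held 37.6% of the class under anti-PD-1 and 20.3% in control. Cluster 7, led by Inhba and Mmp13, held 5.20% and 27.1%.

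In these cells 20 genes rose and 22 fell of 11321 tested. The count of 42 became 8 without control replicate 1, 5 without control replicate 4, and 11, 6, 7 and 0 without anti-PD-1 replicates 1, 2, 3 and 4. Beside it stand 1807 genes at an unadjusted p under 0.05 and 344 called by DESeq2. Without anti-PD-1 replicate 4 the adjusted p of Gbp2b and Il18bp was 0.053. That of Gbp2b was 0.051 without control replicate 1 and 0.062 without control replicate 4. Bhlhe41, Ankrd37, Mmp8, Nuak2 and Smad7 lost their calls without most single libraries (highest adjusted p 0.15, 0.15, 0.19, 0.19 and 0.17). St3gal5 and Irf8 lost theirs without 5 and 4 of the 8 (adjusted p up to 0.096 and 0.088). With the replicate block Irf8 (adjusted p = 0.063), Ankrd37 (0.072), Bhlhe41, Mmp8, Nuak2 and Smad7 (0.087 each) were not called.

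In CD8 T-like cells under anti-PD-1 Irf1, Fgl2 and Iigp1 were higher, and Actn1, Myc and Msmo1 lower. Irf1, a transcription factor of the interferon response (ENSMUSG00000018899, mm10 chromosome 11, 53770014 to 53778374), stood at 208 ± 50.3 CPM against 75.5 ± 8.36 (SD, n = 4). Irf1 rose by 1.46 on the log2 scale (SE 0.20, adjusted p = 6.7e-04). Fgl2, a secreted fibrinogen-like protein (ENSMUSG00000039899, chromosome 5, 21372642 to 21378374), rose from 59.1 ± 17.9 to 174 ± 28.4 CPM (SD, n = 4). Iigp1, of an interferon-induced GTPase, rose from 15.5 ± 3.75 to 43.6 ± 3.13 CPM (SD, n = 4). These changes were 1.46 and 1.38 on the log2 scale (adjusted p = 6.7e-04 for both). Lower were Actn1, which crosslinks actin (ENSMUSG00000015143, chromosome 12, 80167547 to 80260371), at 23.8 ± 5.04 against 66.0 ± 15.4 CPM (SD, n = 4, log2 fold change -1.48, SE 0.20, adjusted p = 6.7e-04). So were the growth regulator Myc (log2 fold change -1.31, adjusted p = 0.0051) and the sterol synthesis gene Msmo1 (-1.25, adjusted p = 0.0011). The 4 libraries of each group did not overlap for these. Of 22 measured interferon gamma response genes 8 rose over all genes and 15 adjusted over the list alone, with a median log2 fold change of 0.77 (adjusted p = 1.3e-19, and adjusted p = 0.0031 with an estimated correlation). This was the one list of the 28 called for anti-PD-1 against control that held with an estimated correlation, and of the 24, 17, 19 and 16 lists called for the other contrasts below none did. Inhibitory receptors and exhaustion genes rose by a median of 0.39, with 2 of 16 higher over all genes and 7 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.33 with an estimated correlation). Among them Tox2, a transcription factor of exhausted T cells, rose by 1.91 and Lag3, an inhibitory receptor, by 0.94 on the log2 scale (adjusted p = 0.0046 and 0.045). Tigit and Entpd1 had log2 fold changes of 1.02 and 0.56 and did not pass over all genes (adjusted p = 0.19 and 0.23). The cytotoxic effector list (median 0.22, adjusted p = 0.080) and the naive and memory T cell list (median -0.71, adjusted p = 0.24) did not pass. Nor did Pdcd1, Gzmb, Prf1, Ifng, Tcf7 and Mki67 (adjusted p between 0.22 and 0.94). Macrophage RNA in these cells had a median of 0.57 (adjusted p = 4.2e-07, and adjusted p = 0.19 with an estimated correlation). Melanoma RNA had one of 0.76 (adjusted p = 0.036, and adjusted p = 0.50 with an estimated correlation). T cell cluster 0 held 55.3% of the class under anti-PD-1 and 41.1% in control. Cluster 9 held 8.46% (7.94% to 9.28%) and 20.1% (13.2% to 28.1%). Of 8798 genes 44 rose and 31 fell. The count of 75 became 32 without control replicate 2, 46 without control replicate 4, 43 without anti-PD-1 replicate 2 and 47 without anti-PD-1 replicate 4. Lag3 lost its call without 7 of the 8 single libraries (adjusted p up to 0.19), and Tox2 without control replicate 2 (adjusted p = 0.056).

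In cDC-like cells 3 genes fell under anti-PD-1: Idi1 and Hmgcs1 of sterol synthesis and the mitochondrial factor Cmc2. Idi1 (ENSMUSG00000058258, mm10 chromosome 13, 8885501 to 8892451) stood at 52.5 ± 13.6 CPM against 126 ± 7.96 (SD, n = 4, log2 fold change -1.26, SE 0.23). Hmgcs1 fell by 1.35 and Cmc2 by 1.69 on the log2 scale. Each of the 3 had an adjusted p of 0.046 and no overlap between the 4 libraries of each group. Type I interferon response genes rose by a median of 0.91, with 2 of 24 higher adjusted over the list alone. Interferon gamma response genes rose by 1.01, with 15 of 21. Over all genes edgeR called 0 in both lists. Their adjusted p was 1.3e-19 and 2.1e-17, and the adjusted p = 0.16 with an estimated correlation for both. T cell RNA in these cells had a median log2 fold change of 0.66, with 0 of 9 genes past the test in either way of adjusting (adjusted p = 0.0036, and adjusted p = 0.40 with an estimated correlation). Cluster 17 held 89.3% of the class under anti-PD-1 (86.5% to 94.2%) and 68.9% in control (57.0% to 81.0%), and cluster 23 the rest. Among 6354 genes 444 had an unadjusted p under 0.05 and DESeq2 called 11. The count of 3 became 15 without control replicate 2 and 0 without control replicates 1, 3 or 4 or anti-PD-1 replicates 1, 3 or 4. It was also 0 with RLE size factors. Idi1 and Hmgcs1 were not called with the replicate block (adjusted p = 0.051 and 0.064).

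In NK-like cells Nfkbia, the inhibitor of NF-kB (ENSMUSG00000021025, mm10 chromosome 12, 55489410 to 55492647), stood at 1252 ± 291 CPM under anti-PD-1 against 387 ± 190 in control (SD, n = 4, log2 fold change 1.54, SE 0.29, adjusted p = 0.0045). The immediate early gene Nr4a1 rose by 1.72 and the adhesion molecule gene Icam1 by 1.63 on the log2 scale (adjusted p = 0.021 and 0.020). Txnip, an inhibitor of glucose uptake, fell by 1.64 (adjusted p = 0.0045). These 4 genes had no overlap between the 4 libraries of each group. Ltb, chosen after its values were seen, completed the 5 changed genes of 3065 with a log2 fold change of -1.56 (adjusted p = 0.0045), and 1 control library lay within the range of anti-PD-1. The TNF and NF-kB response rose by a median of 0.64, with 2 of 14 genes over all genes and 4 adjusted over the list alone (adjusted p = 1.1e-04, and adjusted p = 0.16 with an estimated correlation). The count of 5 became 3, 2, 2, 8, 3 and 2 without control replicates 1, 2 and 3 and anti-PD-1 replicates 1, 3 and 4. Nr4a1 and Icam1 lost their calls most often (adjusted p up to 0.16), Nfkbia without anti-PD-1 replicate 4 (adjusted p = 0.058) or control replicate 3 (0.090), and Ltb without control replicate 2 (0.20). Another grouping of the same 8 libraries called 4 genes, beside the 5 of the real one.

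TBK1i against control asks what the inhibitor did without PD-1 blockade. Ifit1, Ifit2, Ifit3 and Gbp2b fell in monocyte/macrophage-like cells, while Saa3 and Marco rose. Ifit1, an interferon-induced antiviral protein (ENSMUSG00000034459, mm10 chromosome 19, 34640871 to 34650009), stood at 5.84 ± 4.11 CPM against 66.8 ± 23.1 in control (SD, n = 4). Its log2 fold change was -3.55 (SE 0.36, adjusted p = 1.6e-04) and -4.16 without TBK1i replicate 4 (adjusted p = 7.9e-07). Its relatives Ifit2 and Ifit3 fell by 3.90 and 3.71 and Gbp2b fell by 4.95 on the log2 scale (adjusted p = 3.6e-04, 1.6e-04 and 6.1e-04). Isg15 had a log2 fold change of -0.37 and did not pass (adjusted p = 0.79). Saa3, an acute phase protein (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 68.3 ± 88.2 to 943 ± 399 CPM (SD, n = 4, log2 fold change 3.77, SE 0.66, adjusted p = 0.0047). Marco, a scavenger receptor (ENSMUSG00000026390, chromosome 1, 120474538 to 120505024), rose from 17.2 ± 3.47 to 197 ± 93.6 CPM (SD, n = 4, log2 fold change 3.50, SE 0.60, adjusted p = 0.0040). The non-classical MHC gene H2-M2 and Lsmem1 rose by 3.71 and 3.47 on the log2 scale (adjusted p = 0.0040 and 0.0055). The 4 libraries of each group did not overlap for these genes other than Isg15. Gbp2b, Ifit1 and Ifit2 are also among the genes that lead cluster 5 of this class, Saa3 and Marco cluster 0, and H2-M2 cluster 13. Tbk1 itself stood at 36.3 ± 4.61 CPM against 37.6 ± 0.917 (SD, n = 4, adjusted p = 0.84), a transcript level that says nothing of the kinase's activity.

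Of 29 type I interferon response genes 13 fell over all genes and 15 adjusted over the list alone, with a median log2 fold change of -1.01 (adjusted p = 6.5e-12, and adjusted p = 0.32 with an estimated correlation). The interferon gamma response did not pass as a list with all libraries (median -0.11, adjusted p = 0.19), but it was lower without TBK1i replicate 4 (adjusted p = 0.0016). With all libraries it had an adjusted p = 0.845 with an estimated correlation, which was not run without TBK1i replicate 4. TNF and NF-kB response genes rose by a median of 0.83, with 13 of 24 over all genes and 19 adjusted over the list alone (adjusted p = 2.7e-09, and adjusted p = 0.23 with an estimated correlation). Among them rose Ier3 by 1.10, Traf1 by 1.79 and Relb, a subunit of NF-kB, by 0.86 (adjusted p = 0.0057, 0.0063 and 0.014). Proliferation genes fell with a median of -1.0, 4 of 23 over all genes and 21 adjusted over the list alone (adjusted p = 5.6e-10, and adjusted p = 0.32 with an estimated correlation). Mki67, a marker of cycling cells, fell by 1.29 on the log2 scale (adjusted p = 0.025), but not past the test without TBK1i replicates 1 or 4 or control replicates 3 or 4 (adjusted p = 0.056, 0.072, 0.062 and 0.068). The dissociation and immediate early list rose (median 0.31, 5 of 19 genes over all genes, 7 adjusted over the list alone, adjusted p = 0.0019, and adjusted p = 0.23 with an estimated correlation). Inflammatory macrophage genes rose too (median 0.70, 4 of 14 higher and 1 lower over all genes, 5 and 1 adjusted over the list alone, adjusted p = 0.0049, and adjusted p = 0.55 with an estimated correlation). Alternatively activated macrophage genes did not change as a list (median 0.14, mean -0.05, adjusted p = 0.73). MHC class II presentation rose by a median of 0.58, with 0 of 11 genes past the test either way (adjusted p = 0.022, and adjusted p = 0.60 with an estimated correlation). No change passed for RIPK1 and TNF-induced cell death (median 0.06, adjusted p = 0.68) or MHC class I presentation (median 0.02, adjusted p = 0.97). Neutrophil RNA rose in these cells by a median of 2.18 (7 of 11 genes over all genes, 9 adjusted over the list alone, adjusted p = 5.8e-07, and adjusted p = 0.14 with an estimated correlation). It includes Trem1, an activating receptor of myeloid cells, and Il1r2, a decoy receptor of interleukin 1, which rose by 2.30 and 2.18 (adjusted p = 0.0055 and 0.0096). Melanoma RNA had a median of -0.64 (adjusted p = 0.040, and adjusted p = 0.61 with an estimated correlation). Without TBK1i replicate 4 its adjusted p was 0.063. Cluster 5 held 0.79% of the class under TBK1i and 20.3% in control, and cluster 2 held 35.7% and 28.7%. Cluster 3, which holds 60% of the class in TBK1i replicate 4, held 17.5% and 0.31%. In all 610 genes rose and 416 fell, 1026 of 11321. Without TBK1i replicate 4 it was 523, of which 469 were among the 1026. The count was 527, 408 and 504 without control replicates 1, 3 and 4 and 637 without TBK1i replicate 1. Every gene named above except Isg15, Tbk1 and Mki67 kept its call without any single library.

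In cDC-like cells under TBK1i Xcr1 and Cadm1 were lower. Xcr1, a chemokine receptor of cross-presenting cells and one of the markers that named the class (ENSMUSG00000060509, mm10 chromosome 9, 123852315 to 123862029), stood at 16.9 ± 8.01 CPM against 114 ± 28.8 (SD, n = 4, log2 fold change -2.79, SE 0.33, adjusted p = 2.5e-05). Cadm1, an adhesion molecule (ENSMUSG00000032076, chromosome 9, 47530173 to 47857637), stood at 5.41 ± 1.29 against 49.8 ± 21.8 CPM (SD, n = 4, log2 fold change -3.23, SE 0.39, adjusted p = 2.5e-05). The linker histone gene Hist1h1d fell by 2.41 and Mki67 by 1.57 on the log2 scale (adjusted p = 0.0018 and 0.0043). Saa3 rose by 6.08, Pxdc1 by 2.37, S100a8 of neutrophils by 4.70 and the haptoglobin gene Hp by 2.31 (adjusted p = 0.0011, 0.0043, 0.023 and 0.031). For all of these the 4 libraries of each group did not overlap. TNF and NF-kB response genes rose by a median of 0.60, with 4 of 24 over all genes and 11 adjusted over the list alone (adjusted p = 3.4e-08, and adjusted p = 0.18 with an estimated correlation). Among them were Ier3, which rose by 1.2, Il1b by 1.17 and Ptgs2, the prostaglandin synthase, by 1.02 (adjusted p = 0.014, 0.031 and 0.031). Proliferation genes fell with a median of -0.94 (1 of 19 over all genes, 6 adjusted over the list alone, adjusted p = 1.6e-09, and adjusted p = 0.18 with an estimated correlation). Type I interferon response genes had a median of -1.08 (1 of 24 lower over all genes, 10 adjusted over the list alone, adjusted p = 0.0049, and adjusted p = 0.61 with an estimated correlation). Interferon gamma response genes had a median of -0.26 and did not pass as a list (adjusted p = 0.27), but without TBK1i replicate 4 they did (adjusted p = 0.019). With all libraries they had an adjusted p = 0.807 with an estimated correlation. MHC class II presentation, higher in monocyte/macrophage-like cells, had one of -0.49 here (0 of 11 over all genes in edgeR, 3 adjusted over the list alone, adjusted p = 5.7e-05, and adjusted p = 0.23 with an estimated correlation). Neutrophil RNA rose by a median of 2.39 (2 of 8 over all genes, 7 adjusted over the list alone, adjusted p = 5.6e-10, and adjusted p = 0.14 with an estimated correlation). T cell RNA had a median of 0.77 and melanoma RNA one of -1.01, with 0 of 9 and 0 of 6 genes past the test either way (adjusted p = 8.5e-04 and 0.0045, and adjusted p = 0.34 and 0.32 with an estimated correlation). Cluster 17 held 56.4% of the class under TBK1i and 68.9% in control, and cluster 23 the rest. Of 6354 genes 71 rose and 62 fell. The count of 133 became 57, 60 and 50 without control replicates 1, 2 and 3, and 54 and 78 without TBK1i replicates 3 and 4. Single libraries ended the calls of Hp, S100a8, Ier3, Il1b and Ptgs2 (highest adjusted p 0.083, 0.072, 0.077, 0.098 and 0.11).

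In CD8 T-like cells under TBK1i Myc and the linker histone genes Hist1h1a, Hist1h1c and Hist1h1d were lower, and Gpr183, Itgb7 and Emb higher. Myc (ENSMUSG00000022346, mm10 chromosome 15, 61985391 to 61990374) stood at 6.71 ± 4.85 CPM against 68.0 ± 9.33 (SD, n = 4). Myc fell by 3.14 on the log2 scale (SE 0.45, adjusted p = 0.0019). Hist1h1c fell from 308 ± 66.0 to 81.4 ± 29.1 CPM (SD, n = 4, log2 fold change -1.90, SE 0.21, adjusted p = 5.8e-05). Hist1h1d fell by 1.95 and Hist1h1a by 1.89 on the log2 scale (adjusted p = 0.0017 and 0.0054). Gpr183, a receptor for oxysterols (ENSMUSG00000051212, chromosome 14, 121952551 to 121965195), stood at 238 ± 101 CPM against 42.0 ± 9.43 (SD, n = 4, log2 fold change 2.53, SE 0.45, adjusted p = 0.020). The integrin gene Itgb7 rose by 2.16, Emb by 2.10 and Saa3 by 5.40 (adjusted p = 0.0087, 0.029 and 0.0011). The 4 libraries of each group did not overlap for these genes. The naive and memory T cell list rose by a median of 1.24 (2 of 11 over all genes, 5 adjusted over the list alone, adjusted p = 0.0037, and adjusted p = 0.23 with an estimated correlation). Of its genes, Lef1, a transcription factor of naive T cells, rose by 1.79 and S1pr1, a receptor for exit from tissue, by 2.44 (adjusted p = 0.0099 and 0.011), S1pr1 above control in 3 of the 4 libraries. Tcf7 at 1.26 and Pdcd1 at -0.28 did not pass (adjusted p = 0.28 and 0.59). Proliferation genes fell with a median of -0.59, 6 of 23 over all genes and 15 adjusted over the list alone (adjusted p = 2.7e-09, and adjusted p = 0.21 with an estimated correlation). Mki67 fell by 1.06 (adjusted p = 0.019). The cytotoxic effector list did not change (median 0.07, adjusted p = 0.73), nor did inhibitory receptors and exhaustion (median -0.14, adjusted p = 0.55). The dissociation and immediate early list rose by a median of 0.58 (5 of 19 higher and 2 lower over all genes, 8 and 3 adjusted over the list alone, adjusted p = 0.0078, and adjusted p = 0.23 with an estimated correlation). Neutrophil RNA rose by a median of 1.27 over 5 genes (adjusted p = 0.0064, 0.064 without TBK1i replicate 4, and adjusted p = 0.32 with an estimated correlation). Macrophage RNA had a median of 0.16 (adjusted p = 0.016, 0.060 without TBK1i replicate 4, and adjusted p = 0.46 with an estimated correlation). Clusters 0 and 5 of the T cells held 41.1% and 27.6% of the class in control and 17.3% and 6.19% under TBK1i, where cluster 9 held 52.1%. Of 8798 genes 151 rose and 97 fell. The count of 248 became 82, 74 and 85 without control replicates 2, 3 and 4, and 397, 69 and 8 without TBK1i replicates 1, 2 and 3. Gpr183, Emb, Itgb7, Hist1h1a, Lef1, S1pr1 and Mki67 lost their calls without TBK1i replicate 3 (adjusted p = 0.11, 0.13, 0.055, 0.052, 0.11, 0.085 and 0.089). Gpr183 and Emb also lost theirs without TBK1i replicate 2 or control replicates 2, 3 or 4 (adjusted p up to 0.071 and 0.086). Mki67 did so without TBK1i replicate 2 or control replicates 2 or 3 (adjusted p up to 0.056). Myc, Hist1h1c, Hist1h1d and Saa3 kept theirs without any single library.

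In NK-like cells under TBK1i Txnip (ENSMUSG00000038393, mm10 chromosome 3, 96557957 to 96561883) stood at 128 ± 35.9 CPM against 568 ± 327 in control (SD, n = 4). Txnip fell by 2.02 on the log2 scale (SE 0.32, adjusted p = 7.1e-04). Saa3 rose by 4.24 and the myeloid lysozyme gene Lyz2 by 1.74 on the log2 scale (adjusted p = 0.0055 and 0.020), each with no overlap between the 4 libraries of each group. Both are abundant transcripts of myeloid cells. The share of free RNA was not estimated, so whether NK-like cells made them is open, and so it is for Saa3 in cDC-like and CD8 T-like cells and under the combination. TNF and NF-kB response genes rose by a median of 0.83 (1 of 14 over all genes, 7 adjusted over the list alone, adjusted p = 7.6e-04, and adjusted p = 0.18 with an estimated correlation). The list of inhibitory receptors and exhaustion rose by 1.17 (1 of 7 over all genes, 4 adjusted over the list alone, adjusted p = 0.0011, and adjusted p = 0.21 with an estimated correlation). Cluster 10 held 27.2% of the class under TBK1i, 95.1% in TBK1i replicate 4, and 1.1% in control. Of 3065 genes 20 rose and 4 fell. The count of 24 became 1, 6 and 4 without control replicates 2, 3 and 4 and 43, 11 and 3 without TBK1i replicates 2, 3 and 4. Saa3 lost its call without control replicate 2 (adjusted p = 0.17), and Lyz2 without control replicates 2, 3 or 4 or TBK1i replicate 3 (adjusted p up to 0.094). Txnip kept its call without any single library.

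The combination against control compares both treatments with neither, and here the treatment and the library set cannot be told apart. In monocyte/macrophage-like cells Saa3 stood at 1657 ± 585 CPM against 68.3 ± 88.2 (SD, n = 4, log2 fold change 4.58, SE 0.69, adjusted p = 1.3e-04). With the library set as a term its log2 fold change was 3.84 (adjusted p = 0.21). Lsmem1, the nuclear receptor gene Nr4a2 and Amd2 rose by 5.20, 4.37 and 4.35 on the log2 scale. Hist1h1e, the melanoma-associated Ptgds and Mlana, and the lectin gene Clec4b1 fell by 5.08, 4.67, 4.50 and 4.39 on the log2 scale (adjusted p at most 3.9e-04). None of these 7 passed with the set as a term (adjusted p = 0.14, 0.19, 0.36, 0.068, 0.20, 0.18 and 0.14), at log2 fold changes of 3.23, 3.36, 1.31, -2.94, -3.68, -3.98 and -2.96. Ifit3 fell by 3.71 (adjusted p = 1.8e-05). With the set as a term its log2 fold change was -5.33 (adjusted p = 1.0e-04). In cDC-like cells the combination had 3 libraries, because replicate 1 held 12 such cells. There Saa3 and the lipid transporter gene Abca1 rose by 7.53 and 4.42 and Unc119 fell by 3.06 (adjusted p = 1.3e-04, 5.2e-04 and 1.3e-04). These were 7.95, 4.44 and -2.31 with the set as a term (adjusted p = 0.066, 0.58 and 0.58). In NK-like cells Saa3 rose by 5.72 (adjusted p = 1.7e-06, and 0.0082 with the set as a term). The chemokine gene Ccl3 and Hist1h1e fell by 3.48 and 5.01 (adjusted p = 0.0083 and 0.0013). Their log2 fold changes were -2.15 and -2.29 with the set as a term (adjusted p = 1.00 for both). For all of these genes the libraries of the groups did not overlap. In monocyte/macrophage-like cells 19 of 29 type I interferon response genes fell over all genes and 19 adjusted over the list alone (median -1.58, adjusted p = 1.3e-06, and adjusted p = 0.53 with an estimated correlation). Melanoma RNA fell beside them, with 10 of 12 genes lower and 1 higher both over all genes and adjusted over the list alone (median -3.48, adjusted p = 1.2e-04, and adjusted p = 0.37 with an estimated correlation). Neutrophil RNA rose by a median of 1.34 (5 of 11 genes over all genes, 5 adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.37 with an estimated correlation). In cDC-like cells it rose by 2.87 (3 of 8 over all genes, 4 adjusted over the list alone, adjusted p = 0.0035, and adjusted p = 0.37 with an estimated correlation). Clusters 0 and 3 held 61.9% and 23.3% of the monocyte/macrophage-like class under the combination and 0.31% each in control. NK cluster 10 held 91.4% of its class against 1.1%. In all 2640 genes rose and 2606 fell in monocyte/macrophage-like, 441 and 436 in cDC-like and 167 and 118 in NK-like cells. With the set as a term 10, 2 and 1 genes were called. Without combination replicate 3 the cDC-like count of 877 was 481. The NK-like count of 285 was 185 and 186 without control replicates 2 and 3.

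The combination against anti-PD-1 asks what the inhibitor added to PD-1 blockade, again on the side of the library set. In monocyte/macrophage-like cells Gbp2b stood at 1.32 ± 1.25 CPM against 154 ± 23.2 (SD, n = 4). Its log2 fold change was -6.52 (SE 0.57, adjusted p = 7.2e-06). It was also called with the set as a term (log2 fold change -8.07, adjusted p = 0.029). Cxcl10, a chemokine that draws T cells (ENSMUSG00000034855, mm10 chromosome 5, 92346638 to 92348889), stood at 162 ± 120 against 539 ± 115 CPM (SD, n = 4, log2 fold change -1.74, SE 0.50, adjusted p = 0.011). Nos2, the inducible nitric oxide synthase, fell by 1.95 and Cd274, the gene of PD-L1, by 0.90 on the log2 scale (adjusted p = 0.011 and 0.033). The set term left Cxcl10, Nos2 and Cd274 at larger log2 fold changes of -2.495, -2.58 and -1.80, which were not called (adjusted p = 0.16, 0.19 and 0.11). In Nos2 and Cd274, combination replicate 4 lay inside the range of anti-PD-1 and the other 3 below it. Cd274 lost its call without 6 of the 8 libraries (adjusted p up to 0.099). Saa3 and Fbxo32 rose by 4.58 and 4.19 and Retnla and Mlana fell by 6.12 and 5.32 (adjusted p = 1.6e-04, 5.0e-05, 0.0023 and 1.5e-04). None of these was called with the set as a term (adjusted p = 0.16, 0.10, 0.95 and 0.082). Saa3, Fbxo32 and Mlana then had log2 fold changes of 3.85, 3.14 and -4.79, and that of Retnla turned to 1.69. In cDC-like cells Saa3 rose by 6.49 and the interferon-induced Isg20, Cd180 and Rtp4 fell by 3.17, 3.04 and 2.89 (adjusted p = 2.5e-04, 0.0020, 2.6e-04 and 0.016). These were 6.92, -4.12, -2.91 and -3.33 with the set as a term and not called (adjusted p = 0.14, 0.17, 0.25 and 0.45). Rtp4 was not called without combination replicates 3 or 4 (adjusted p = 0.073 and 0.066). In NK-like cells Ifng, the gene of interferon gamma (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), stood at 47.3 ± 18.2 against 247 ± 125 CPM (SD, n = 4, log2 fold change -2.37, SE 0.42, adjusted p = 5.2e-04). The cytolytic genes Prf1 and Gzmb fell by 1.25 and 1.17, Ccl3 by 3.88 and the melanoma transcript Dct by 6.36, while Saa3 rose by 5.74 (adjusted p = 0.0012, 0.015, 0.0046, 0.0051 and 1.5e-08). The set term left Ifng, Prf1, Gzmb, Ccl3 and Dct at -1.27, -0.85, -0.37, -2.54 and -5.07 (adjusted p = 1.00 for each) and Saa3 at 5.83 (adjusted p = 0.0017). Cluster 3 held 97.3% of this class under anti-PD-1 and 8.56% under the combination, and cluster 10 the rest. Gzmb was not called without combination replicate 4 or anti-PD-1 replicate 1 (adjusted p = 0.066 and 0.054).

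Of 29 type I interferon response genes 27 were lower in monocyte/macrophage-like cells over all genes and 28 adjusted over the list alone (median -2.21, adjusted p = 5.3e-13, and adjusted p = 0.37 with an estimated correlation). Interferon gamma response genes fell with a median of -1.16, 14 of 25 in both ways, over all genes and adjusted over the list alone (adjusted p = 4.0e-05, and adjusted p = 0.66 with an estimated correlation). Melanoma RNA fell in the same cells with a median of -4.13, 10 of 12 genes lower and 1 higher both over all genes and adjusted over the list alone (adjusted p = 1.5e-05, and adjusted p = 0.37 with an estimated correlation). T cell RNA had a median of -1.18 there and did not pass (adjusted p = 0.063). In NK-like cells the cytotoxic effector list fell with a median of -0.72, 4 of 16 genes over all genes and 8 adjusted over the list alone (adjusted p = 3.9e-05, and adjusted p = 0.37 with an estimated correlation). Melanoma RNA fell there with a median of -6.95 (2 of 4 over all genes, 4 adjusted over the list alone, adjusted p = 2.7e-06, and adjusted p = 0.22 with an estimated correlation). In cDC-like cells TNF and NF-kB response genes rose by a median of 0.85 (11 of 24 over all genes, 14 higher and 2 lower adjusted over the list alone, adjusted p = 1.1e-04, and adjusted p = 0.37 with an estimated correlation). Neutrophil RNA rose there by a median of 1.88 (2 of 8 over all genes, 3 adjusted over the list alone, adjusted p = 0.0055, and adjusted p = 0.41 with an estimated correlation). Melanoma RNA fell in the same cells with a median of -4.09 (0 of 6 over all genes, 5 adjusted over the list alone, adjusted p = 5.1e-04, and adjusted p = 0.37 with an estimated correlation). Cluster 5 held 37.6% of the monocyte/macrophage-like class under anti-PD-1 and 0.34% under the combination, and cluster 17 held 89.3% and 57.1% of the cDC-like class. The 57.1% averages 4 combination libraries that ranged from 19.0% to 91.7%. Among them is replicate 1, which had 12 such cells and was not tested. Counts of genes higher and lower were 2573 and 2550 in monocyte/macrophage-like, 546 and 539 in cDC-like and 129 and 114 in NK-like cells. With the set as a term 136, 1 and 1 genes were called. The cDC-like count of 1085 was 468 without combination replicate 3. The NK-like count of 243 was 151 without anti-PD-1 replicate 1 and 155 without combination replicate 2. Of the 1026 genes that TBK1i changed in monocyte/macrophage-like cells against control, 931 (90.7%) moved the same way between the combination and anti-PD-1, a comparison that shares no libraries with the first. Of the 523 genes called without TBK1i replicate 4, 517 were also tested in the fit of all libraries, and 459 of these (88.8%) moved the same way, while the reverse reading, of the 5123 genes called here, gave 77.5%. For cDC-like cells the share was 96.2% of 133 genes and for NK-like cells 87.5% of 24.

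The interaction asks whether the inhibitor's effect differed with and without anti-PD-1, and it too rests on the library set. For monocyte/macrophage-like cells 662 genes were higher and 676 lower than the sum of the single effects. With the set as a term edgeR called 0 genes, beside 3426 at an unadjusted p under 0.05 and 1919 called by DESeq2 without that term. In NK-like cells the 3 genes with an interaction were Nfkbia, Icam1 and Nr4a1, with log2 values of -2.34, -2.51 and -2.35 (adjusted p = 0.0034, 0.012 and 0.034). With the set as a term 0 were called there too. In cDC-like cells edgeR called 0 genes, beside 930 at an unadjusted p under 0.05 and 94 called by DESeq2. The lists lower in the interaction of monocyte/macrophage-like cells included the type I interferon response (median -0.74, 5 of 29 genes over all genes, 11 adjusted over the list alone, adjusted p = 5.7e-04, and adjusted p = 0.63 with an estimated correlation). Melanoma RNA was lower as well (median -3.59, 7 of 12 genes over all genes, 10 lower and 1 higher adjusted over the list alone, adjusted p = 3.0e-05, and adjusted p = 0.61 with an estimated correlation). T cell RNA had a median of -1.17, with 0 of 10 genes past the test either way (adjusted p = 0.0028, and adjusted p = 0.61 with an estimated correlation). The count of 1338 became 846, 887 and 644 without control replicates 1, 2 and 4 and 729, 765 and 877 without anti-PD-1 replicates 1, 2 and 4. It became 702 and 2062 without TBK1i replicates 2 and 4, and 615 and 717 without combination replicates 2 and 3. The cDC-like count of 0 became 1, 84 and 245 without anti-PD-1 replicate 3, TBK1i replicate 4 and combination replicate 4. The NK-like count of 3 became 6 without anti-PD-1 replicate 1 or TBK1i replicate 2, 20 without TBK1i replicate 4, 5 without combination replicate 3 and 1 without anti-PD-1 replicate 4, TBK1i replicate 1 or combination replicate 4.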

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

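All tests of explanations in this part were chosen after the result was seen.

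The 5 libraries set apart, TBK1i replicate 4 and the combination, share a pattern in ribosomal protein transcripts. An effect of the inhibitor is argued against by TBK1i replicates 1 to 3, whose highest SD of log2 deviations in monocyte/macrophage-like cells was 0.247. A difference between library batches predicted the same deviations in other classes of a library. In the 5 libraries the lowest r between another class and the monocyte/macrophage-like cells was 0.82. In the other libraries r ranged from -0.057 to 0.884. A mislabelled TBK1i replicate 4, with an effect of the combination in all classes, would predict the same. The test therefore does not single out a batch. Whether TBK1i replicate 4 was mislabelled and is a combination library cannot be told apart from a batch shared with them. Its CD8 T share of 0.796% lay below 3.06% to 3.49% in TBK1i replicates 1 to 3 and above 0.082% to 0.647% in the combination. Its melanoma RNA of 746 CPM lay below 3542.6 to 8199.5 CPM in TBK1i replicates 1 to 3 and above 96.2 to 378 CPM in the combination. Its gamma-delta T share of 0.059%, from 4 cells, lay within 0.030% to 0.172% in TBK1i replicates 1 to 3. That share lay below the lowest value of the combination, 0.359%. NK cluster 10 held 95.1% of its class in this library, within the 83.3% to 95.9% of the combination.

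The CD8 T share was lower under TBK1i than in control. CD8 T cells left among unresolved T cells because CD8 transcripts were missed are argued against, as the share of both together differed by -9.73 percentage points without TBK1i replicate 4 (5.18% ± 0.86, SD, n = 3, against 14.9% ± 1.18, SD, n = 4, exact two-sided permutation p = 0.029). Clusters of mixed cells, left out of that share, held 6.40% of retained cells under TBK1i and 1.97% in control, untested for CD8 T cells. Equal dilution of CD8 T and regulatory T-like cells is argued against by their log2 ratio, which differed by -2.34. Regulatory T-like cells were 3.80% against 2.26% (exact permutation p = 0.11), and dilution by growing classes stays open. The median UMI count of T-like cells differed by -1034 (2571 ± 637, SD, n = 3, against 3605 ± 1213, SD, n = 4, exact two-sided permutation p = 0.29). Shallower T cells lost before naming therefore cannot be told apart from fewer CD8 T cells.

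The type I interferon response fell in monocyte/macrophage-like cells under TBK1i. Without TBK1i replicate 4 the 15 genes that fell had medians of -1.55, -2.02, -0.99 and -1.66 on the log2 scale within clusters 2, 7, 10 and 13, where the class as a whole had -2.74. Another mix of clusters, as the whole or part of the cause, cannot be told apart from a change within cells, since over all 29 measured genes the mean log2 CPM differed by -1.24, -1.76, -0.20 and -1.26 in the same order (exact two-sided permutation p = 0.057, 0.029, 0.77 and 0.029). Less interferon beta transcript stays open as a route: Ifnb1, at 0.436 ± 0.797 CPM against 8.82 ± 3.30 (SD, n = 4), had a log2 fold change of -3.65 without TBK1i replicate 4 (adjusted p = 0.048 in edgeR), but missed the test with DESeq2 (0.10), without a filter (0.065), without TBK1i replicate 1 (0.051), without control replicate 4 (0.052) and without both replicates 4 (0.095). It stood at 0.546 ± 0.691 CPM under anti-PD-1 too (SD, n = 4, log2 fold change -3.82, adjusted p = 0.098), where the interferon lists were higher.

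Other groupings of the same libraries show whether chance can be excluded. For anti-PD-1 against control the real grouping alone, 1 of 35, gave its count of 42 genes in monocyte/macrophage-like, 3 in cDC-like, 75 in CD8 T-like and 5 in NK-like cells, and the highest other counts were 0, 0, 9 and 4. For TBK1i against control 1 of 35 gave 1026, 133, 248 and 24 in the same order, and the highest others were 5, 12, 0 and 1. For the combination against control 1 of 35 gave 5246, 877 and 285 in monocyte/macrophage-like, cDC-like and NK-like cells (highest others 0, 47 and 23), and against anti-PD-1 1 of 35 gave 5123, 1085 and 243 (highest others 0, 17 and 12). Counts of gene lists stood out less: 2 of 35 groupings gave 28 or more for anti-PD-1 (highest other 29) and 3 of 35 gave 24 or more for TBK1i (highest other 31), so that chance is not excluded there. For the combination 1 of 35 gave 17 lists against control (highest other 16) and 1 of 35 gave 19 against anti-PD-1 (highest other 18). Groupings for the interaction mix treatments and the library set, whose own effects can then enter it, so they cannot decide on chance. Of 100 groupings, 3 gave 1338 genes or more in monocyte/macrophage-like cells (highest other 2685). In cDC-like cells 100 gave 0 or more (highest other 29), in NK-like 7 gave 3 or more (122), and 20 gave 16 lists or more (20).

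In 279 groups of 4 samples tested, 30 samples lay far from the others of their group, where chance flags about 1 in 20 groups, or 13.9. Among shares and library measures these were the CD8 T share in TBK1i replicate 4 (0.796%), NK-like cells in control replicate 2 (7.25%), the log2 lymphoid to myeloid ratio in combination replicate 3 (-3.19), and stromal RNA in control replicate 2 (459 CPM), anti-PD-1 replicate 3 (1123 CPM) and TBK1i replicate 3 (169 CPM). Control libraries of monocyte/macrophage-like cells held Saa3 and Cd274 in replicate 1 (200.5 and 208 CPM), Lsmem1 and Ifit3 in replicate 2 (3.33 and 78.6 CPM), Clec4b1 in replicate 3 (179 CPM) and H2-M2 in replicate 4 (9.63 CPM). In the same cells of treated libraries they were Tbk1 in anti-PD-1 replicate 1 (36.7 CPM), Ankrd37 in anti-PD-1 replicate 3 (21.1 CPM), and Il1r2 in TBK1i replicate 1 (46.0 CPM). Also far from the others were Ifnb1 in TBK1i replicate 3 (1.63 CPM), Ifit2, Ifit3 and Ifit1 in TBK1i replicate 4 (16, 7.46 and 12 CPM), Lsmem1 in combination replicate 2 (106 CPM) and Fbxo32 in combination replicate 4 (46.0 CPM). In cDC-like cells they were Xcr1 in control replicate 3 (70.3 CPM), Rtp4 in anti-PD-1 replicate 3 (47.4 CPM) and Ier3 in TBK1i replicate 2 (529 CPM). In CD8 T-like cells they were Gzmb and Prf1 in control replicate 1 (2166 and 1316 CPM) and Iigp1 in anti-PD-1 replicate 2 (48.3 CPM). In NK-like cells they were Txnip in control replicate 4 (1053 CPM), Saa3 in anti-PD-1 replicate 1 (11.3 CPM) and Dct in combination replicate 4 (3.60 CPM).

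The effect of the inhibitor differed with and without anti-PD-1 by the edgeR interaction term for 1338 genes in monocyte/macrophage-like and 3 in NK-like cells, with the library set on the side of the combination, and for 0 in either with the set as a term. Among named genes of monocyte/macrophage-like cells the log2 interaction was -5.05 for Ptgds (adjusted p = 0.014), -4.53 for Mlana (0.018), -2.5 for Marco (0.049), -2.12 for Hist1h1e (0.036), -1.85 for Traf1 (0.025), -0.95 for St3gal5 (0.039) and -0.84 for Irf8 (0.034). It was 2.91 for Fbxo32 (adjusted p = 0.021), 1.88 for Bhlhe41 (0.023) and 1.51 for Mmp8 (0.022). In NK-like cells it was -2.51 for Icam1, -2.34 for Nfkbia and -2.35 for Nr4a1 (adjusted p = 0.012, 0.0034 and 0.034 in edgeR).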

How the results depend on the processing

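The tests here that were chosen after seeing the data are the library set as a term, unresolved T cells counted as CD8 T, TBK1i replicate 4 and control replicate 4 left out together, and the same-sign share without TBK1i replicate 4. Of 241 values of 29 results under another setting, single libraries left out not counted, 182 stayed within 1.5 times and 59 did not. Of 117 named genes, 100 passed the threshold. Among the named genes Retnla alone turned its sign, with the library set as a term. The cause was not tested for the counts below, except that the set term leaves TBK1i replicate 4 alone to separate set from inhibitor and that fits on fewer libraries have fewer residual degrees of freedom. No contrast or interaction with CD8 T-like cells of the combination was run, since 3 of its 4 libraries held fewer than 20. Whether low depth in the combination limited the resolved T cells was not tested.

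In monocyte/macrophage-like cells the count of 42 for anti-PD-1 was 344 with DESeq2, 88 with the set term, 503 with only the groups of the contrast, 70 at up to 20% mitochondrial UMIs and 14 at a higher clustering resolution. The 1026 for TBK1i was 530 with the set term, 549 with only its groups and 244 without both replicates 4. With the set term the combination gave 10 against control and 136 against anti-PD-1, and the interaction 0. In cDC-like cells the 3 for anti-PD-1 was 11 with DESeq2, 1 with the set term, 0 with RLE, 86 without a filter, 17 with only its groups and 0 at 500 genes or more. The 133 for TBK1i was 75 with the set term, 395 without a filter and 66 without both replicates 4, the combination gave 2 and 1 with the set term, and the interaction 94 with DESeq2 and 96 without a filter. In CD8 T-like cells the 75 for anti-PD-1 was 314 without a filter and 117 with only its groups, and the 248 for TBK1i was 407 with DESeq2, 553 without a filter and 95 without both replicates 4. In NK-like cells the 5 for anti-PD-1 was 19 without a filter. The 24 for TBK1i was 39 with DESeq2, 4 with the set term, 72 without a filter, 3 at 500 genes or more and 4 without both replicates 4. The combination gave 1 and 1 with the set term, and the interaction 5 with DESeq2, 0 with the set term and 27 without a filter. The same-sign share of 90.7% was 88.3% with DESeq2. With an estimated correlation 1 list was called for anti-PD-1 and 0 for the other contrasts. At an unadjusted p under 0.05 the shares called for anti-PD-1 were 5 in an edgeR test of cell numbers and 5 at the higher resolution, against 3. For the antibody averaged over the inhibitor shares were counted at an adjusted p under 0.05. They were 5 in that test, 4 at up to 20% mitochondrial UMIs, 4 at the higher resolution, 1 over all retained cells and 4 with unresolved T cells as CD8 T, against 2. In that edgeR test the CD8 T effect of the averaged antibody turned its direction, at a log2 fold change of -1.07 (p = 0.0070) against 6.39 percentage points in the permutation test (exact p = 0.029, adjusted p = 0.070). The CD8 T share was higher with the antibody without the inhibitor (25.5% against 10.4%) and lower with the inhibitor (0.286% against 2.71%). The sign of the average therefore depends on the scale.

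Replicate numbers do not pair the samples: r between libraries of 1 number was over 0.1 in 5 of 24 pairs of monocyte/macrophage-like, 2 of 21 of cDC-like, 0 of 12 of CD8 T-like and 4 of 24 of NK-like cells. A block for the number gave 6 genes in monocyte/macrophage-like cells for anti-PD-1, 566 in cDC-like cells for the combination against control and 8 in NK-like cells for TBK1i. For shares it gave 5 for anti-PD-1, 3 for TBK1i averaged and 1 for anti-PD-1 averaged. In the other 22 of 28 fits the block stayed within 1.5 times.

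Leaving out single libraries, counts in monocyte/macrophage-like cells ranged from 0 to 59 for anti-PD-1, 408 to 1267 for TBK1i, 4657 to 5186 for the combination against control, 4182 to 4967 against anti-PD-1 and 615 to 2062 for the interaction. In cDC-like cells the ranges in that order were 0 to 15, 50 to 159, 481 to 954, 468 to 1173 and 0 to 245, and in NK-like cells 2 to 8, 1 to 43, 185 to 325, 151 to 301 and 1 to 20. In CD8 T-like cells they were 32 to 74 and 8 to 397. Lists ranged from 25 to 33, 23 to 28, 14 to 17, 14 to 20 and 12 to 18. Shares ranged from 1 to 5, 2 to 4, 4 to 6 and 6 to 8, and for the averages from 5 to 7 for TBK1i and 2 to 4 for anti-PD-1. The same-sign share was 88.8% without TBK1i replicate 4.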

Other observations

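No test of an explanation was chosen for this part. Among T-like cells Cd8a and Cd8b1 together stood at 967 CPM in control, 1259 under anti-PD-1, 568 under TBK1i and 547 under the combination, with an exact two-sided permutation p of 0.029 for TBK1i against control (0.057 without TBK1i replicate 4, at 600 CPM). Over whole libraries Cd8a stood at 49.2, 115, 18.5 and 25.5 CPM. Against control the exact permutation p was 0.029, 0.086 and 0.17 for anti-PD-1, TBK1i and the combination.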
